A study of Zea mays with 94 samples.

How the data were processed

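Leaves of 5 week old maize plants, grown in hydroponics with 16 h of light at 26 °C and 8 h of darkness at 22 °C, gave total RNA for paired-end mRNA libraries, per the labels' protocols. Reads were quality trimmed and aligned with TopHat2 to the B73 reference V2 and the working gene set V5a, per the labels' protocols; CASAVA, Cufflinks and Cuffdiff are also named, per the submitters' processing notes, and their versions are not given in the sources used here. The authors deposited FPKM values per transcript for all 94 libraries in 1 table. The genotype labels assigned 3 libraries to B73, 3 to Mo17 and 88 to DH lines, and every column matched 1 library, with 0 columns of other samples.

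A gene was taken as the gene of the nearest known transcript, and its FPKM as the sum of its transcripts. 1571 known transcripts were blank in every library, and the 1570 genes with several transcripts that held a blank were left out of isoform tests, which leaves 24427 genes. FPKM are not counts, so no count test was used. Among 21095 genes with 1 transcript, 43.2% of low values lay within 0.1 of a whole step, against 20% for evenly spread values. The step of each gene and a scale of each library were fitted to these same values. The fit draws values toward whole steps, so 20% is not its chance level. Only relative depth was estimated. An FPKM of 0 can be a failed estimate, and such genes are given as listed at 0.

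Gene levels were compared as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (trend and robust settings), for genes with a mean of at least 1 FPKM in B73 or Mo17; a fold change on this scale understates the change of low genes. Isoform shares were compared as log2((FPKM + 0.1)/(rest of gene + 0.1)) without trend, for genes with at least 2 FPKM and transcripts with a mean share of 5 to 95%. P-values were adjusted by Benjamini and Hochberg's method and called at 0.05. Variance among DH lines was tested with an F test against limma's moderated within-parent variance. The DH mean was tested against the midparent with 3 group means and a spread pooled over the groups. For these tests of gene levels, genes had a mean of at least 1 FPKM over all libraries. Lists of at least 4 measured genes were tested with camera and fry. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

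Gene names and neighbours came from a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0, a different build from that of the authors. Its coordinates were not used, so the distance classes planned in megabases were replaced by classes in genes, with bounds of 15, 75, 300 and 750 genes; 17848 genes were placed. Unnamed models were placed from the order of transcript numbers in the table, checked on 17779 genes, of which 99.3% fell on the reference chromosome and 97.2% within 15 genes. Lists defined by descriptions (splicing factors, heat shock, pathogenesis, disease resistance and histone genes) were not run, as descriptions are not used here.

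The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named the 10 largest differences in each direction between parents among genes with separated libraries and at least 5 FPKM, list members that passed, the 8 largest share differences in each direction with 1 transcript per gene, the 8 largest F values and the 5 largest differences from the midparent in each direction; the text prints some of them. Other genes printed are list members or were chosen after their values were seen. Alternatives changed pseudocounts, filters, scaling, variance settings, the replicate block and left out each parental library.

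The tests of gene levels, isoform shares, variance among lines, the midparent and linkage were tested on simulated data; the tests of gene lists were not. Between parents, 36 of 100 genes changed by log2 2 and 79 of 100 changed by log2 5 were recovered, with 13 false calls among 40381 genes. For isoform shares, 0 of 100 changes of log2 4 and 37 of 100 of log2 8 were recovered, with 1 false call among 37291 transcripts. For variance among lines, 15 of 100 genes with a 3 times larger SD and 99 of 100 with an 8 times larger SD were recovered (9 false calls among 41556), and 18 and 98 of 100 transcripts (1 false call among 50235). Replicate values in these simulations were drawn from normal distributions with the moderated spreads, so recovery in the real data can be lower. Between parents it can also be higher, since only 200 genes or transcripts were changed, which makes the adjusted threshold stricter. Of the changes of log2 2 in genes and log2 4 in shares, 92 and 80 of 100 had an unadjusted limma p under 0.05. Against the midparent, 172 of 200 changes of log2 2 were recovered with 47 false calls among 41556 genes, so that a part of the genes that pass this test can be false. With the spread of parents and lines estimated apart, 185 of 200 were recovered with 38 false calls.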

Results

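Leaf RNA was sequenced from 94 maize libraries to describe alternative splicing and its genetic regulation. They comprised 3 libraries of the inbred line B73, 3 of the inbred line Mo17 and 1 from each of 88 doubled-haploid (DH) lines of the intermated B73 by Mo17 population Syn10. A DH line is fixed for 1 parental allele at each locus. The values were FPKM (mapped fragments relative to transcript length and to the library's total) of 231404 transcripts, of which 139325 belonged to the maize working gene set and 92079 were assembled outside it. Transcripts were summed to 109729 genes. FPKM sums ran from 1117873 to 1800543 per library (median 1201351), and the replicate 2 library had the highest sum of its parent in B73 (1748732) and Mo17 (1712021). Read totals are unknown, and relative depth estimated from the lowest values ran from 0.749 to 1.365 around a median of 1, with 0.974 to 1.1 in B73 and 1.08 to 1.17 in Mo17. For some tests the span of library numbers was divided into 3 equal parts, each with 1 replicate of each parent, called the 3 sets of library numbers below; the labels state no batches. Nothing in the labels says whether replicates were separate plants, so p-values measure the spread between these libraries, which may be technical.

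Most expressed genes with several listed transcripts had more than 1 of them at a measurable level. In B73, 12744 of 18048 such genes (70.6%) had at least 2 transcripts at a mean of 1 FPKM or more. The shares were 69.4% in Mo17 (12366 of 17820) and 71.9% over the DH lines (13173 of 18330). The leading transcript held a median of 65.7% of gene FPKM in B73, 67.3% in Mo17 and 63.5% in the DH lines. Transcripts outside the gene set carried 32.1%, 33.1% and 32.3% of FPKM in B73, Mo17 and the DH lines, in that order. These values are descriptive and were not tested between groups.

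The first comparison asked which genes differed in level between the parents, with differences given as Mo17 minus B73 on the log2(FPKM + 0.5) scale. The largest difference among the listed genes was that of bx1 (GRMZM2G085381), which encodes the first enzyme of benzoxazinoid defence metabolism. It measured 5.03 ± 3.31 FPKM in B73 and 1678 ± 462.3 FPKM in Mo17 (SD, n = 3 each; log2 difference 8.49, SE 0.61, limma adjusted p = 0.000229). Of 12 benzoxazinoid genes, 8 were measured, 3 rose in Mo17, 1 fell and 4 did not pass, and 4 passed when adjusted over the list alone. bx2 (GRMZM2G085661) rose from 0.435 ± 0.191 to 6.15 ± 2.35 FPKM (log2 difference 2.78) and bx5 (GRMZM2G063756) from 23.1 ± 5.31 to 54.95 ± 10.7 FPKM (1.24). bx7 (GRMZM2G441753), a methyltransferase gene of the same pathway, fell by 1.54 on the log2 scale, from 63.3 ± 11.4 to 22.3 ± 8.51 FPKM.

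Genes of C4 photosynthesis were lower in Mo17 where they passed. pep1 (GRMZM2G083841), the phosphoenolpyruvate carboxylase of mesophyll cells, had 1486 ± 448.8 FPKM in B73 and 441.2 ± 83 in Mo17 (SD, n = 3 each; log2 difference −1.73, SE 0.27, limma adjusted p = 0.00604). It was the only 1 of 6 mesophyll genes to pass the threshold for size and p, over all genes; pdrp1 (GRMZM2G131286) had adjusted p = 0.0426 with a log2 difference of 0.78, under the minimum of 1. Adjusted over the list alone, 1 mesophyll gene passed. Of 7 bundle sheath genes, 3 fell and none rose, both over all genes and adjusted over the list alone. These were the rubisco small subunit genes ssu1 (GRMZM2G098520; 1060 ± 168.7 and 309.8 ± 123.4 FPKM in B73 and Mo17) and ssu2 (GRMZM2G113033; 1991 ± 184.5 and 784.7 ± 356.3) and the malic enzyme gene me3 (GRMZM2G085019; 2696 ± 232.3 and 1345 ± 274.8). After quantile normalization ssu1 kept its call, while me3 lost it (log2 difference −0.96, under the minimum of 1), as did ssu2 (adjusted p = 0.0501). The rubisco activase gene rca1 (GRMZM2G162200) did not pass (log2 difference −0.08).

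Among 14 anthocyanin genes, 8 were measured and 2 fell in Mo17, both also when adjusted over the list alone. bz2 (GRMZM2G016241), a glutathione transferase gene needed for pigment transport, had 5.40 ± 0.995 FPKM in B73, while its Mo17 libraries were listed at 0.0655, 0 and 0.196 (log2 difference −3.33, limma adjusted p = 0.000729). fht1 (GRMZM2G062396), a flavanone hydroxylase gene, had 1.31 ± 0.399 FPKM in B73 and 0, 0 and 0.0729 in Mo17 (log2 difference −1.77, adjusted p = 0.0443). B73 replicate 2 stood above the other B73 libraries for c2 (GRMZM2G422750; 64.3 against 9.32 and 13.3 FPKM) and pr1 (GRMZM2G025832; 39.1 against 0.298 and 9.02), and neither passed. Of 8 light-harvesting genes, lhcb6 (GRMZM2G092427) rose from 238.7 ± 57.2 to 519.3 ± 83.4 FPKM (log2 difference 1.14) and was the only 1 to pass, also over the list alone. lhcb_c (GRMZM2G018627) had adjusted p = 0.0252 in the other direction, with a log2 difference of −0.93, under the minimum of 1. Of 6 measured nitrogen assimilation genes, the nitrite reductase gene nii2 (GRMZM2G079381) rose from 26.0 ± 3.09 to 66.2 ± 16.0 FPKM (1.31). Adjusted over the list alone, 2 nitrogen genes passed, the other being gln2 (GRMZM2G098290, log2 difference 1.18, adjusted p = 0.0691 over all genes). Over all genes, gln2 passed the limma test after quantile normalization (1.14, adjusted p = 0.0265) and median scaling (1.11, adjusted p = 0.0367).

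None of the 9 circadian, 6 measured flowering-time or 4 carotenoid genes passed, over all genes or adjusted over the list alone. The morning clock genes cca1 (GRMZM2G474769) and lhy1 (GRMZM2G014902) differed widely between replicates. cca1 had 26.5, 33.6 and 9.36 FPKM in B73 replicates 1, 2 and 3 and 84.7, 34.6 and 9.60 in those of Mo17. Of the terpenoid defence genes only tps2, tps3 and tps23 were measured; none passed over all genes, and tps3 (GRMZM2G064406) passed adjusted over the list alone (log2 difference 2.08, adjusted p = 0.0362). The 4 knox genes, markers of meristem and stem, were below the filter, with kn1 (GRMZM2G017087) highest at 0.442 FPKM in B73 and 0.793 in Mo17.

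**Figure D1:**
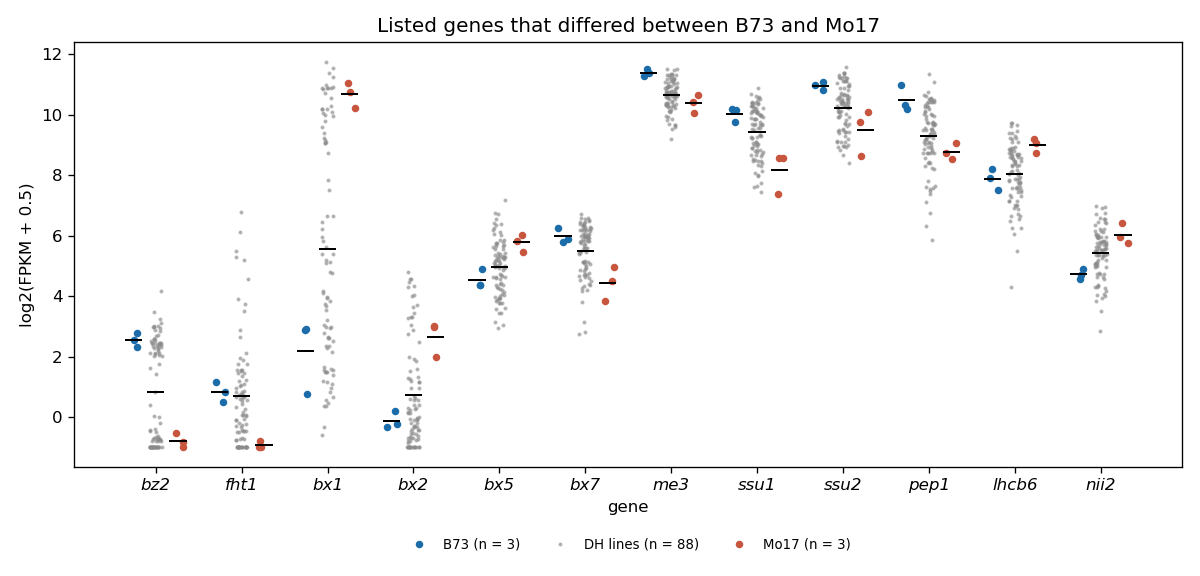
Level of the 12 listed genes that passed between the parents, as log2(FPKM + 0.5), in B73 (n = 3), Mo17 (n = 3) and the 88 DH lines; each point is 1 library and each bar a group mean. For bx1 the DH lines ran from 0.166 to 3453 FPKM, past the parental means of 5.03 and 1678.

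Over all genes, 7290 of 44053 tested (16.5%) passed the limma test at an adjusted p of 0.05 and a log2 difference of at least 1. Of these, 3891 were higher in Mo17 and 3399 in B73, so that 53.4% were higher in Mo17, against 47.8% after quantile normalization, which moved the median log2 difference of all genes from 0.105 to 0.009. All 7290 had non-overlapping libraries, an arrangement that chance gives for 10% of genes. The largest differences belonged to unnamed gene models listed at 0 in 1 parent. GRMZM2G539681 was listed at 0 in each B73 library and at 1531, 1741 and 1470 FPKM in Mo17, and GRMZM2G518225 at 399.3, 471.3 and 504.6 FPKM in B73 and at 0 in each Mo17 library. In all, 1190 of the genes that passed were listed at 0 in all B73 libraries and 675 in all Mo17 libraries. Among genes named in the reference table, 1309 of 13969 (9.37%) passed, and 41.8% of these were higher in Mo17; among unnamed models 19.9% passed, with 55.9% higher in Mo17. The count fell to 4827 with a filter of 5 FPKM and to 3776 without the replicate 2 library of both parents, and was 11562 with library weights. Leaving out 1 parental library ended the call of fht1 in 6 of 6 cases (log2 difference −1.93 to −1.61), and those of 4 genes in all cases but 2. The exceptions were the cases without B73 replicate 3 or Mo17 replicate 2 for bx5 (1.11 to 1.42), B73 replicate 2 or Mo17 replicate 1 for lhcb6 (0.95 to 1.30) and me3 (−1.16 to −0.86), and Mo17 replicates 1 or 3 for ssu2 (−1.76 to −1.03). bx7 (−1.81 to −1.24) lost its call without replicate 2 of either parent or B73 replicate 3, and ssu1 (−2.06 to −1.46) and nii2 (1.13 to 1.46) without B73 replicate 3. bx1, bx2, bz2 and pep1 kept theirs in all 6 cases. Without the replicate 2 library of both parents fht1, bx5, bx7, lhcb6, me3, ssu1 and ssu2 lost theirs. Library weights ended the calls of bx5 and me3, the absence of a filter or of a variance trend that of ssu2, and the replicate number as a term in the fit that of fht1.

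As groups, no list passed the camera test with a preset correlation of 0.01. Adjusted p was 0.0838 for benzoxazinoid genes (higher in Mo17) and for anthocyanin and bundle sheath genes (lower), and these 3 lists had an unadjusted p under 0.05. With an estimated correlation, adjusted p = 0.69 for the first 2 and 0.687 for bundle sheath genes. By fry, which tests whether the genes of a list move on balance one way, the same 3 lists passed, each with adjusted p = 0.0326. Mesophyll, carotenoid, flowering, light-harvesting and nitrogen lists had a camera adjusted p of 0.585 each, and the circadian list 0.85.

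The second comparison asked where the parents differed in isoform share, the percentage of a gene's FPKM held by 1 transcript. In several genes the FPKM of the parents were assigned almost completely to different transcripts. Mo17 reads were aligned to the B73 reference, and the effect of this on shares and gene levels was not tested. In GRMZM2G017966 the transcript GRMZM2G017966_T02 held 100% of the 39.3 FPKM in B73 and 0.00516% ± 0.000307 of the 87.7 FPKM in Mo17, where GRMZM2G017966_T01 held 99.99% (SD, n = 3 each; limma adjusted p = 0.00283). GRMZM2G081012 had close totals, 19.9 FPKM in B73 and 17.9 in Mo17, but its annotated transcript held 100% in B73 and 0.000267% in Mo17, the rest falling to a transcript outside the gene set (adjusted p = 0.00313). Similar exchanges were seen in GRMZM2G700063, GRMZM2G058888, GRMZM2G129737 and GRMZM2G178913. GRMZM2G132995 gave almost all of its FPKM in Mo17 to a transcript outside the gene set that was near 0 in B73.

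In total 1119 of 43468 transcripts tested in 14034 genes passed at an adjusted p of 0.05 and a difference of 10 percentage points, 594 of them higher in Mo17 and the rest in B73. They lay in 836 genes (5.96%). In 272 genes the difference reached 50 points, and in 488 genes another transcript led. Transcripts outside the gene set were higher in Mo17 in 348 of 606 cases, and annotated ones, fewer in number, in 246 (Fisher's exact test, two-sided, p = 0.00177, odds ratio 1.46; transcripts of 1 gene are not independent). Of the 836 genes, 233 also differed in gene level, against 65.94 for independent lists; both comparisons used the same 6 libraries, so part of the excess may come from shared values. Leaving out 1 library gave 659, 501 and 257 transcripts without B73 replicates 1, 2 and 3 and 108, 137 and 343 without those of Mo17. The call of GRMZM2G132995 was lost without B73 replicate 3 and Mo17 replicates 2 and 3, and that of GRMZM2G700063 without Mo17 replicate 1. Their share differences stayed at 100 points in size with each library left out where tested. With the replicate number as a term in the limma fit, which leaves fewer degrees of freedom, 0 transcripts passed, those named above included (lowest adjusted p 0.157; 4391 with an unadjusted p under 0.05). A trend in the variance gave 520 transcripts, the percent scale 532 and a filter of 10 FPKM 745.

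The third comparison asked which genes varied more among DH lines than among parental replicates. The genes with the largest ratios were models listed at 0 in 1 parent, and many lines were listed at 0 as well. A parent listed at 0 in all its libraries adds no spread to the within-parent variance, which can favour such genes in this ranking. GRMZM2G539681 had an SD of 5.07 on the log2 scale among the lines and 0.20 within parents (F = 674.8, adjusted p = 0.000205), with 28 lines listed at 0 and a highest value of 2042 FPKM. GRMZM2G518225 (F = 414.7) was listed at 0 in 43 lines. Of the listed genes, bx1 had an SD of 3.82 among lines and 0.75 within parents (F = 25.9, adjusted p = 0.00644), and bz2 had F = 20.6 (adjusted p = 0.00939). bx2, bx3, bx5, pep1, nii2, 4 light-harvesting genes (lhcb6 among them) and the terpenoid genes tps2, tps6 and an2 also passed. fht1 reached 108.9 FPKM among the lines against 1.31 FPKM in B73 (F = 20.3, adjusted p = 0.00964). No circadian, bundle sheath or carotenoid gene passed.

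Over all genes, 4424 of 41556 (10.6%) passed the F test against limma's moderated within-parent variance, and 11494 had an unadjusted p under 0.05. The median SD was 0.702 among lines and 0.44 within parents, and 79.3% of genes had the larger variance among lines. The count was 1214 when libraries were centred within the 3 sets of library numbers, which also leaves fewer degrees of freedom, and 24246 with no filter on low values. It was 2215 without B73 replicate 3 and 2399, 2454 and 2654 without Mo17 replicates 1, 2 and 3.

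Isoform shares varied among lines in named genes, but none passed the same F test. Among the 88 lines GRMZM2G017966_T02 held over 90% of its gene in 51, under 10% in 28 and a value between in 9. The B73 transcript of GRMZM2G081012 was over 90% in 36 lines, under 10% in 46 and between in 6. That of GRMZM5G820287 was over 90% in 47, under 10% in 32 and between in 9, and that of GRMZM2G058888 over 90% in 22 and under 10% in 55 of the 78 lines with at least 1 FPKM. By the moderated F test 0 of 50235 transcripts passed, while 7970 had an unadjusted p under 0.05 and 70% had a larger variance among lines. The count was 532 with a pseudocount of 0.02, 2470 on the percent scale and 20 with the median absolute deviation.

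**Figure D2:**
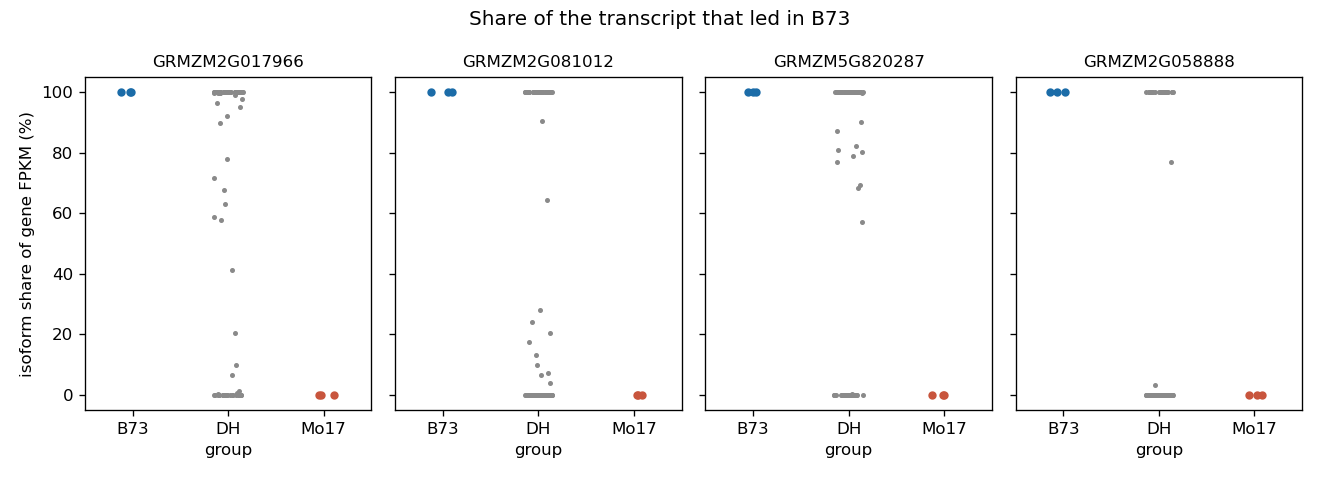
Percentage of gene FPKM held by the transcript that led in B73, for 4 named genes, in B73 (blue), the DH lines with at least 1 FPKM of the gene (grey) and Mo17 (red); each point is 1 library. For GRMZM2G058888 55 lines were under 10% and 22 over 90%.

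The fourth comparison asked whether the mean of the DH lines differed from the midparent, the mean of both parents. GRMZM2G571798, listed at 0 in B73 and at 303.6, 122.5 and 212.1 FPKM in Mo17, reached 0.5 FPKM in only 5 of 88 lines (log2 difference from the midparent −4.11, SE 0.36, limma adjusted p = 2.01e-15). GRMZM2G530704 and GRMZM2G580126, also listed at 0 in B73, reached it in 4 and 2 lines. GRMZM2G548306, with 41.1, 52.6 and 29.9 FPKM in B73, lay lower in the lines by −3.28. In the other direction, GRMZM2G170693 was at 36.4, 31.4 and 33.4 FPKM in B73 and near 0 in Mo17, and all 88 lines reached 0.5 FPKM (log2 difference 2.77, adjusted p = 1.32e-13). GRMZM2G390009, listed at 0 in each Mo17 library, also reached it in 88 lines (2.89).

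In total 99 of 41556 genes passed, 31 above and 68 below the midparent, at an adjusted p of 0.05 and a difference of at least 0.5, and 81.2% of genes lay within 0.5. The count was 163 and 51 without B73 replicates 1 and 2, 65 and 56 without Mo17 replicates 1 and 2, 34 with a filter of 5 FPKM, 636 with none and 1295 with the spread of parents and lines estimated apart, 55 of the 99 among them. The direction depended on the setting: 18 genes lay above and 16 below with the 5 FPKM filter, 25 and 26 without B73 replicate 2, 48 and 54 with a pseudocount of 0.1, and 44 and 58 after median scaling. With no filter 63 lay above and all others below. Leaving out 1 parental library ended the calls of GRMZM2G070041 in 6 of 6 cases (log2 difference 2.57 to 2.61) and of GRMZM2G506168 (2.76 to 3.63) without B73 replicate 3 or Mo17 replicates 1 or 2. GRMZM2G519381 (−3.89 to −2.32) lost its call without replicate 2 of either parent or Mo17 replicate 1, and also with the spreads estimated apart.

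The last comparisons asked whether parental differences were passed on by chromosome region. Genes that differed between parents varied together among the lines when they were neighbours. For 867 pairs of 1309 named genes no more than 15 genes apart, Pearson's r over the 88 lines, signed so that positive means covariation in the parental direction, averaged 0.386. It averaged 0.278 up to 75 genes apart, 0.13 up to 300, 0.052 up to 750, 0.015 beyond and 0.011 between chromosomes (permutation test of gene positions, one-sided, p = 0.0001, the smallest that 10000 shuffles give). Spearman's rho averaged 0.361 for the nearest pairs, and r 0.39 after centring within the 3 sets of library numbers. For 572 transcripts that differed in share, r with the level of other genes averaged 0.314 up to 15 genes apart (778 pairs) and 0.005 between chromosomes (p = 0.0001, again the smallest possible). In the order of transcript numbers, which covers unnamed models, the nearest pairs of genes averaged 0.163 and those of shares and genes 0.182.

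**Figure D3:**
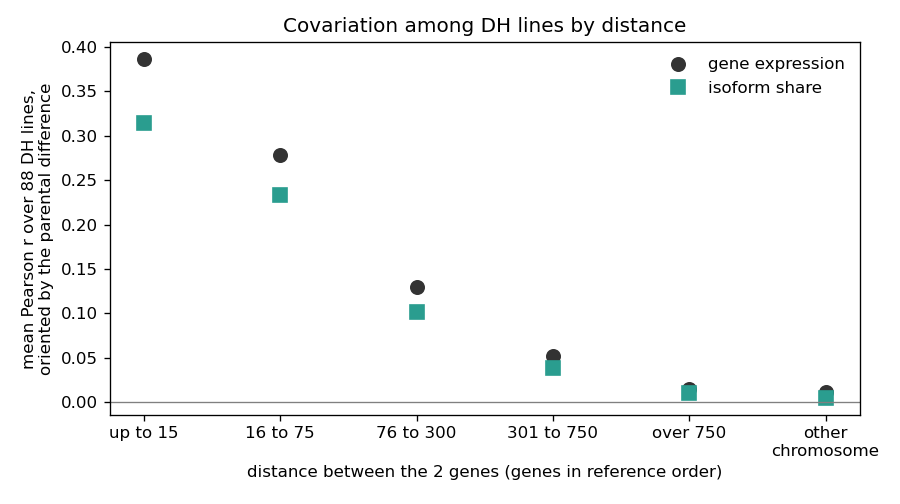
Mean Pearson r over the 88 DH lines, signed by the parental difference, against the distance between the 2 genes, counted in genes of the reference order. Circles are pairs of genes and squares pairs of an isoform share and another gene; both fall from the nearest class (0.386 and 0.314) to pairs on different chromosomes (0.011 and 0.005).

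A single locus with equal allele numbers would give a variance among lines, beyond that of replicates, equal to the square of 0.5 of the parental difference. The ratio of the measured to that value had a median of 0.777 over 7290 genes (quartiles 0.526 and 1.07), and 65.7% of genes lay between 0.5 and 1.5. These genes were selected by the parental difference in the same parental libraries, which can enlarge that difference and lower the ratio. bx1 was on the B73 side of the midparent in 53 lines and on the Mo17 side in 35 (exact binomial test, two-sided, adjusted p = 0.118), bz2 in 43 and 45 (adjusted p = 0.938). bx2 was on the B73 side in 63 and on the Mo17 side in 25 (adjusted p = 0.000284). Over 4754 genes with a log2 difference of at least 2, the median share of lines on the B73 side was 54.5% (quartiles 43.2 and 65.9), and 2124 genes differed from an even split, 1469 of them toward B73. Over the 539 of these genes named in the reference table the median was 52.3%. Sides were taken from gene levels and not from alleles, so an uneven count need not mean uneven transmission. For bx2 the B73 level was also low (0.435 FPKM).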

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

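The tests of separate spreads, of genes named in the reference table, of both replicate 2 libraries together and those on the order of transcript numbers, neighbours under 3 genes apart, 1 transcript per gene and parental libraries left out of linkage, ratio and transmission were chosen only after the data were seen. Of the main values, 86 kept the result and 32 moved. For linkage, keeping it means the direction and the side of the test threshold, not the size. For counts it allows sizeable change, as 4920 genes between parents without Mo17 replicate 1 counted as kept against 7290. For the variance ratio and the B73-side share the bound was a spread of the left-out values themselves, so these could hardly move. In the order of transcript numbers, which adds unnamed models, linkage was lower (0.163 for genes and 0.182 for shares, against 0.386 and 0.314) and still passed (p = 0.001 and 0.0001); the cause was not tested. Among named genes, 514 of the parental log2 values kept their call and 41 lost it; 204 and 21 did so for shares, 111 and 1 for variance among lines, 123 and 13 for the midparent. No value of a named gene or transcript reversed direction in these settings. The balance of directions over all genes did turn, with 3587 higher in Mo17 and 3922 in B73 after quantile normalization.

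Genes differing between parents numbered 4827 with a 5 FPKM filter, 11562 with library weights, 3776 without both replicate 2 libraries and 1309 when only named models were kept; fewer genes were tested with the filter and the named models, and for the others the cause was not tested. Leaving out 1 library gave 4920 to 6521. Transcripts with a different share numbered 745 with a 10 FPKM filter, 520 with a variance trend and 532 on the percent scale, and 108 to 659 with 1 library left out (659, 501 and 257 without B73 replicates 1, 2 and 3; 108, 137 and 343 without those of Mo17). Genes varying among lines numbered 24246 with no filter and 1214 when centred within the 3 sets of library numbers, and 2215 to 3364 with 1 library left out. Variable shares numbered 532 with a pseudocount of 0.02, close to 1.2e2 with a 10 FPKM filter, 2470 on the percent scale and 20 with the median absolute deviation, and 0 to 0 with 1 library left out. Genes away from the midparent numbered 636 with no filter, 34 with a 5 FPKM filter and 1295 with separate spreads, and 51 to 163 with 1 library left out. By fry 3 lists passed, against 0 by camera, whose estimated-correlation form also gave 0. The cause was not tested for these. Linkage of genes (0.387 to 0.486) and shares (0.286 to 0.367), the variance ratio (0.745 to 0.794) and the B73-side share (53.4 to 56.8%) had these ranges with 1 library left out.

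With the replicate number as a block, 6777 genes, 0 transcripts and 0 lists passed; 4391 transcripts had an unadjusted limma p under 0.05, against 5003 without the block, and the lowest adjusted p was 0.157. Deviations of same-numbered parental libraries correlated at 0.065, 0.094 and 0.075, under 0.1, so the numbers were not taken to pair the libraries, although each library correlated best with its own number. The log2 level of cca1 and lhy1 against toc1a and toc1b differed by 2.77 between lines in the first and last of the 3 sets of library numbers. This clock gene difference leaves open that the numbers mark shared handling. FPKM sums were highest in replicate 2 of B73 (1748732) and Mo17 (1712021), which the lines did not share. DH lines 42, 43 and 44, numbered between these libraries, had 1214773, 1218884 and 1196899. If the numbers do mark shared handling, the block would be the better design, under which no isoform share passes. Unknown read totals limit what can be said of genes listed at 0.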

Other observations

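The tests of terpenoid pairs, of models listed at 0 following their neighbours, of handling of the parents and of other splits were chosen only after the result was seen; those of depth and of unequal transmission were written before their results, and that of the clock genes after the parental values but before those of the DH lines.

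In some DH lines, listed terpenoid defence genes exceeded all 6 parental libraries. tps6 (GRMZM2G127087), a terpene synthase gene, was between 0 and 1.22 FPKM in the 6 parental libraries, but its highest DH line had 493.9 FPKM, and 30 lines had at least 5 FPKM while 15 were listed at 0. an2 (GRMZM2G044481), a diterpene synthase gene of the kauralexin branch, had a median of 0.925 and a highest value of 246.5 FPKM, with 21 lines at 5 FPKM or more. tps10 (GRMZM2G179092) was listed at 0 in the 6 parental libraries and in 58 lines, with 92.98 FPKM in the highest of the 2 lines at 5 or more. The highest line had 144.1 FPKM for tps2, 80.37 for tps3 and 15.78 for tps23, against 17.37, 13.42 and 11.3 in the highest parental library. For tps6 and an2 the variance among lines passed the F test (tps6 F = 29.2, adjusted p = 0.00515, and an2 F = 14.1, adjusted p = 0.0192), and the means did not pass against the midparent (adjusted p = 0.816 and 0.87). Both genes had means under 1 FPKM in B73 and in Mo17 and entered these tests only through the lines where they were high.

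Among the 15 pairs of the 6 listed terpenoid genes, an2 and tps6 rose and fell together over the 88 lines (Pearson's r = 0.934, Spearman's rho = 0.896, permutation p = 1e-05 for each, the smallest possible, adjusted p = 7.5e-05; r = 0.941 without the 2 farthest lines and 0.948, 0.939 and 0.909 within the 3 consecutive sets of library numbers). tps2 (GRMZM2G046615) and tps3 (GRMZM2G064406) formed another such pair (r = 0.922, rho = 0.909, permutation p = 1e-05, adjusted p = 7.5e-05; 0.914 without the 2 farthest lines and 0.989, 0.945 and 0.833 within the sets), whose values are uncertain if these related genes share reads. Between the 2 pairs r was −0.202 to −0.113 and no relation passed, but the sets differed (0.001 to 0.108 in the first, −0.434 to −0.339 in the second and −0.371 to −0.024 in the last). tps10 and tps2 had r = 0.314 (rho = 0.291, permutation p = 0.00289 and 0.00622, adjusted p = 0.0145 and 0.0311; 0.268 without the 2 farthest lines and 0.215, 0.398 and 0.344 within the sets), and tps10 and tps3 passed by r (0.26, adjusted p = 0.0446; 0.192 without the 2 farthest lines) but not by rho (0.211, adjusted p = 0.185).

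The clock genes cca1, lhy1, toc1a and toc1b differed between replicates of both parents, which was described and not tested. The order was not the same for each gene (cca1 was highest in B73 replicate 2 but in Mo17 replicate 1). Other listed circadian genes were not part of the score that follows. A score of morning genes (cca1, lhy1) minus evening genes (toc1a, toc1b), as mean log2(FPKM + 0.5), was −0.26, −1.53 and −2.58 in B73 replicates 1, 2 and 3 and 2.26, −0.53 and −2.59 in those of Mo17. The 3 sets of library numbers each hold 1 replicate of each parent, and the DH lines of the first set (n = 30) exceeded those of the last (n = 31) by 2.77 (0.27 ± 0.89 against −2.50 ± 0.67, permutation test, two-sided, p = 1e-05, the smallest possible). This fits a difference between sets of libraries shared by parents and lines, for which the time of harvest is a candidate source; the labels give no harvest time, and growth or handling of the sets stays open. No biological explanation was tested.

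Models listed at 0 in all B73 libraries and higher in Mo17 followed their neighbours less often among the lines than models listed at 0 in Mo17. Following was defined as r of at least 0.4 with named genes up to 40 genes away. Of 902 models at 0 in B73, 129 (14.3%) followed, against 43.8% of 557 at 0 in Mo17 (Fisher's exact test, two-sided, p = 2.65e-35). Nearby models share neighbours, so they are not independent and this p-value can be too small. Among models above 0 in both, 1836 of 4353 (42.2%) followed. The lower share at 0 in B73 may come from reads of loci elsewhere in the genome placed on the model. Of the non-followers at 0 in B73, 62.4% instead followed a window on another chromosome, against 55.3% of those at 0 in Mo17. Among non-followers above 0 in both it was 68.6%, so this value does not settle it. A difference in depth is argued against: the median Spearman correlation with relative depth over lines was 0.024 (quartiles −0.049 and 0.091). Regulation from another chromosome and Mo17 sequence that lies elsewhere stay open as untested.

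Of the 99 genes away from the midparent, 41 differed between the parents, 36 of them nearer to B73 in the lines and 5 nearer to Mo17. Unequal transmission of the region may contribute: neighbouring genes were shifted toward the same parent by a median of 10.6 percentage points, past the 10 set beforehand. The bootstrap interval was 4.0 to 23, however, and only 17 of the 41 genes had neighbours. The shift was counted from an even split, although named genes already lay at a median of 52.3% on the B73 side, so part of it can be this general lean. Parental plants handled apart from the lines cannot be told apart from a biological difference, as 58 genes without a parental difference also lay away from the midparent (42 lower, 16 higher). Parents and lines share the sets of library numbers and the clock difference between them, and no label names a separate set of parental plants. In FPKM sums, replicate 2 of B73 (1748732) and Mo17 (1712021) stood above the median of the lines (1196946). B73 replicates 1 and 3 (1183443 and 1206656) lay near that median, and the highest line had 1800543. The labels give no record of growth or handling, so separate handling of the parents stays open.

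Other splits of the same libraries bear on the counts. For the parents, 3 against 3 libraries make only 10 splits, too few for a share under 0.05. The real split gave 7290 genes and 1119 transcripts and the highest other 19 and 0. Every other split mixes B73 and Mo17 libraries, so the parental difference widens the spread within groups and keeps those counts low. For variance among lines 1 of 100 splits was as large, the real one (4424 against 125 in the highest other). Other splits place different lines in the replicate groups, so this shows only that parental replicates varied less than lines. It does not bear on single calls. For the midparent 1 of 100 splits was as large, the real one (99 against 52 in the highest other). Those splits also place different lines in the parental groups, so they do not exclude chance as the source of the count. The real count also fell to 51 without B73 replicate 2 and to 34 with a filter of 5 FPKM. Part of the 99 can be false, since a simulation with 200 changed genes gave 47 false calls beside 172 true ones. For variable isoform shares the splits can say nothing: the real count was 0, so 100 of 100 splits gave at least as many, and the highest other gave 2.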
